A study of Mus musculus with 23 samples.

How the data were processed

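Libraries were made, per the labels, from total RNA of perfused livers with a stranded mRNA kit. Per the labels the authors used bcl2fastq 2.16, TopHat2 2.0.8, Partek (version not given) and the mm10 build. The annotation, counting settings and strand setting are not given in the sources used here. The authors deposited estimated counts per gene symbol for 24440 genes, of which 6462 were at 0 in every library and 88.3% to 94.1% of values in a library were whole. The authors also deposited log2 values for 14078 genes. These matched log2 of rounded CPM plus 1, shifted by a constant per library from -0.1418 to 0.04106, with upper quartiles of 5.242 to 5.251 (100% of values whole within 0.01 once the constant was removed).

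The deposited estimated counts were rounded to whole numbers and read with edgeR 4.0.16 in R 4.3.3. Library totals, in units of 1e6 counts, ran from 7.11 to 30.2, with 16.2 to 30.2 in dKO_chow and 7.79 to 8.94 in IL4KO_HFD. Correlations between replicate libraries ran from 0.9504 to 0.9898. edgeR's filter by group left 12891 genes. Scaling used trimmed mean of M values, and 1 robust quasi-likelihood fit held the 6 group means of all 23 libraries, with 17 residual degrees of freedom and a biological coefficient of variation of 0.156. The 9 pairs were the diet effect in each genotype and each pair of genotypes on each diet, and the 3 interactions were differences between diet effects. Tests were two-sided with Benjamini-Hochberg adjustment over all tested genes at 0.05, and over each list for counts adjusted over the list alone. CPM (counts scaled to library size) use the same scaling.

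The 33 gene lists, fixed before the data were examined, were tested with camera from limma 3.58.1, which compares a list with all other genes, with a preset correlation of 0.01 and adjustment over the lists of a comparison. Of 178 list calls, 4 held with a correlation estimated from the data, namely lipogenesis in dKO against WT on HFD and lipogenesis, circadian clock and adipocyte markers in the IL4KO minus WT interaction. fry was run beside it, and its p tests whether the genes of a set move on balance one way without comparing them with other genes. No called list had a median, mean and test that differed in sign. Those of some lists not called did, most often adipocyte and erythroid markers and bile acid genes, such as erythroid markers in dKO against WT on chow (median 0.757, mean 0.492, test down). Fgb is in the acute phase and hepatocyte lists, and Cyp7b1, Slco1a1 and Creb3l3 are each in a pair of lists. Named genes were the targeted genes, up to 8 per direction by size among called genes with a mean of at least 2 CPM in the higher group and no overlap of CPM, and up to 4 members of each list that was called or had at least 3 called members. For interactions they were up to 5 genes per direction by FDR. Predicted genes were left out. Gene positions were matched for 24316 symbols, and Fisher's exact test compared calls within 10 Mb of Il4 and Il10 with all other tested genes. Reads of near-identical paralogs (Mup, Cyp2c, Serpina1, Ren1 and Ren2, Cyp2a4 and Cyp2a5, Cyp2b9 and Cyp2b13) cannot be assigned with certainty from gene counts.

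Alternatives fixed before the data were examined were RLE and upper quartile factors, no filter and a strict filter, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, a fit without robust estimation, limma on the deposited log2 values, the estimated correlation, fry, windows of 5 and 20 Mb and leaving out each library in turn. Chosen after seeing the data were thinning to the smallest library, leaving out dKO_HFD replicate 4 and IL4KO_HFD replicate 3 together, the scan of 10 Mb bins, the split tests of the pairs and the tests for libraries far from their group. IL4KO_HFD replicate 2 stood further from its group than replicate 3 on the components, and is left out on its own among the single libraries.

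The pipeline was tested on simulated data with planted changes. At 1.5-fold, 2-fold and 4-fold it recovered 49.3%, 84.8% and 92.3% of planted genes in the diet effect in WT, 41.8%, 75.8% and 87.5% in the diet effect in IL4KO, and 22.4%, 63.6% and 87.3% in the dKO minus WT interaction, with 7.45%, 3.6% and 4.27% of calls false. A planted list was called in all 4 comparisons, and the window test gave p below 0.05 for 7 of 200 random sets. With 200 genes planted, broader shifts and correlation within real lists went unchecked. Exon use, splicing and reads outside genes could not be studied from gene counts. Results for some named genes are not reported here.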

Results

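The series holds 23 liver RNA-seq libraries from male mice of 3 labelled genotypes, each fed chow or a high-fat diet for 15 weeks. The groups are wild type (WT), IL-4 knockout (IL4KO) and IL-10/IL-4 double knockout (dKO), on chow or on the high-fat diet (HFD). Each group holds 4 mice, except IL4KO_HFD with 3, and the mice are separate animals. A total of 12891 genes were tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment, and genes at FDR below 0.05 are called. The comparisons, gene lists, thresholds and the rule for naming genes were fixed before the data were examined. Fold changes are log2, levels are CPM as mean ± SD, and the standard error (SE) of a log2 fold change is its absolute value divided by the square root of F.

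The targeted genes came first. Il4 had 0 to 3 counts in a library in every group and was not tested, so its counts check little. Il10, which encodes an anti-inflammatory cytokine, was higher in the libraries labelled dKO, against the direction of the label. Its counts were 41 to 67 in dKO_chow libraries and 6 to 21 in dKO_HFD libraries, but 0 to 2 in WT_chow, 0 to 4 in WT_HFD, 0 to 2 in IL4KO_chow and 0 in IL4KO_HFD. The level was 2.34 ± 0.476 CPM in dKO_chow against 0.087 ± 0.101 CPM in WT_chow (FDR 3.1e-05) and 0.0464 ± 0.0927 CPM in IL4KO_chow (FDR 3.62e-05), with n of 4 in each group. On HFD it was 0.803 ± 0.591 CPM in dKO against 0.12 ± 0.134 CPM in WT (FDR 0.0108), and at least 6.72-fold higher than in IL4KO_HFD, where a floor of 3 counts over the group stood in for 0 (FDR 0.0347). Gene-level counts do not show which exons were deleted, so they do not test the deletion, and every statement about dKO refers to libraries labelled dKO. The call of Il10 in dKO against WT on HFD was lost with the deposited log2 values (FDR 0.0508) or after thinning (FDR 0.15). The call of Il10 in dKO against IL4KO on HFD was lost without IL4KO_HFD replicate 1 (FDR 0.119), IL4KO_HFD replicate 2 (FDR 0.177) or dKO_HFD replicate 4 (FDR 0.0687), with the log2 values (0.143) or after thinning (0.0701). Nnt, which is mutated in one C57Bl/6 substrain, was read in every group at mean levels of 114 to 212 CPM.

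The first principal component of log2 CPM held 39% of the variance and set dKO_chow apart, with scores of -74.76 to -64.64. dKO_HFD replicates 1 to 3 scored 10.2 to 17.2, near WT and IL4KO, and dKO_HFD replicate 4 scored -43.1. The second component held 18% of the variance, and the 3 IL4KO_HFD libraries spread along it at 14.09, 54.54 and -16.6.

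**Figure D1:**
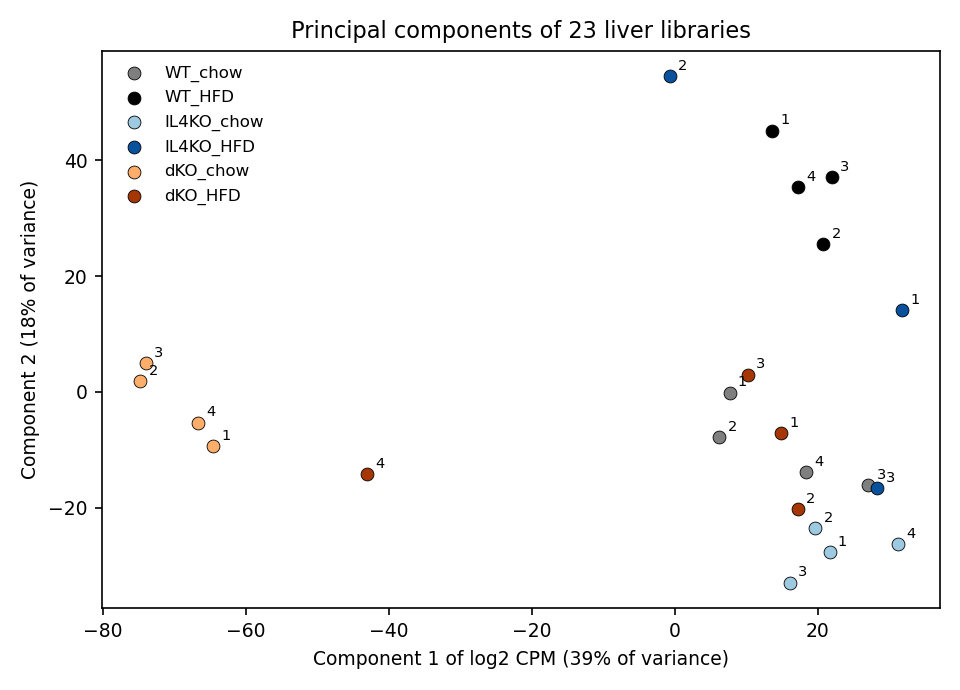
Scores of 23 liver libraries on component 1 (horizontal, 39% of variance, no unit) and component 2 (vertical, 18% of variance, no unit) of log2 CPM, 1 point per mouse, coloured by group and numbered by replicate. The 4 dKO_chow libraries lie at -74.76 to -64.64 on component 1 and dKO_HFD replicate 4 at -43.1.

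The number of called genes ranged from 6 to 5966 between the 12 comparisons. The diet effect called 2511 genes in WT and 1170 in IL4KO, and IL4KO differed from WT at 1239 genes on chow and 389 on HFD.

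**Figure D2:**
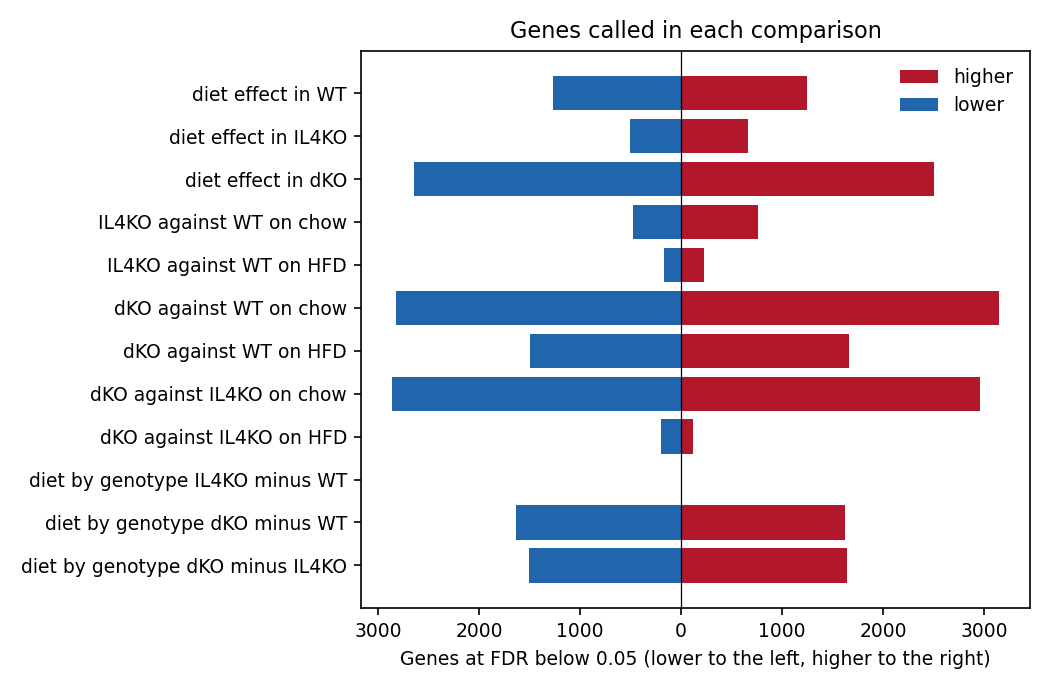
Bars give the number of genes at FDR below 0.05 in each of 12 comparisons (horizontal axis, genes), with lower genes to the left of 0 and higher genes to the right. dKO against WT on chow has the longest pair of bars, with 3148 higher and 2818 lower genes.

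The diet effect in WT asks what HFD changes in a normal liver. Lipid storage genes rose with it. Of 21 measured genes of lipid droplets and PPARG targets, 12 rose and 0 fell, and 14 rose adjusted over the list alone (camera adjusted p = 1.76e-08; adjusted p = 0.362 with an estimated correlation). Pparg, a driver of fat storage, rose by 1.41 (SE 0.235, FDR 0.000444), from 9.11 ± 0.744 to 24.3 ± 5.84 CPM, and the fatty acid binding protein gene Fabp4 rose from 13.4 ± 3.94 to 50.4 ± 11.5 CPM. Of 24 genes of de novo lipogenesis, 11 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.26e-06; adjusted p = 0.362 with an estimated correlation). Fads2, a fatty acid desaturase gene, went from 411 ± 50.6 to 949 ± 114 CPM (FDR 2.09e-05), Gpam, an enzyme of triglyceride synthesis, rose by 1.05 (SE 0.143), and Mlxipl, which encodes the regulator ChREBP, fell by 0.55 (FDR 0.000951). Of 28 genes of fatty acid oxidation and PPARA targets, 14 rose and 0 fell, and 19 rose adjusted over the list alone (camera adjusted p = 4.9e-07; adjusted p = 0.55 with an estimated correlation). Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, rose by 0.52 (SE 0.112), from 467 ± 31 to 671 ± 60.7 CPM.

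Matrix and proliferation genes also rose in the diet effect in WT. Of 42 genes of extracellular matrix and stellate cell activation, 16 rose and 0 fell, and 25 rose adjusted over the list alone (camera adjusted p = 8.04e-09; adjusted p = 0.55 with an estimated correlation). Col1a1 was at 32.1 ± 15.6 against 5.25 ± 1.82 CPM (FDR 0.0135), and the TGF-beta receptor gene Tgfbr2 at 44.1 ± 5.61 against 27.7 ± 4.57 CPM (FDR 0.000968). Of 28 cell cycle genes, 13 rose and 0 fell, and 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.15e-08; adjusted p = 0.362 with an estimated correlation). Of 15 female-biased liver genes 10 rose and 0 fell, while of 21 male-biased liver genes 0 rose and 4 fell (camera adjusted p = 1.6e-05 and 1.7e-05; adjusted p = 0.373 and 0.55 with an estimated correlation). Cyp2b9, a female-biased gene with near-identical paralogs, went from 16.4 ± 15.1 to 254 ± 143 CPM, and the male-biased Elovl3 fell from 404 ± 229 to 68 ± 22.6 CPM (FDR 0.00114). Of 19 circadian clock genes 11 rose and 4 fell (camera adjusted p = 0.0018; adjusted p = 0.362 with an estimated correlation). On HFD Per3 was higher (28.5 ± 5.46 against 5.01 ± 2.38 CPM) and Arntl lower (4.09 ± 1.43 against 16.9 ± 4.07 CPM, FDR 2.9e-05). Clock calls in any comparison may reflect hour of collection (not given). Of 21 NRF2 targets 6 rose and 0 fell (camera adjusted p = 0.0148; adjusted p = 0.64 with an estimated correlation). Genes outside these lists included Srgap3, down from 5.07 ± 1.62 to 0.538 ± 0.215 CPM (FDR 1.13e-06), Irs1, an insulin receptor substrate, down by 0.98 (SE 0.115), and Cyp1a2, down from 594 ± 57.9 to 255 ± 64.1 CPM.

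The remaining lists of the diet effect in WT passed narrowly or not at all. In the type I interferon response 6 of 29 genes rose and 0 fell (camera adjusted p = 0.0052; adjusted p = 0.708 with an estimated correlation). In the unfolded protein and integrated stress response 1 of 27 genes rose and 6 fell (camera adjusted p = 0.00582; adjusted p = 0.64 with an estimated correlation). Monocyte-derived and lipid-associated macrophage markers had 1 of 21 genes higher (camera adjusted p = 0.0288; adjusted p = 0.872 with an estimated correlation), and the interferon gamma response and antigen presentation had 5 of 40 higher (camera adjusted p = 0.0431; adjusted p = 0.922 with an estimated correlation). Hepatocyte markers had 4 of 17 lower (camera adjusted p = 0.0431; adjusted p = 0.64 with an estimated correlation). Without WT_chow replicate 3 the adjusted p was 0.0766 for the list type I interferon response in diet effect in WT, 0.132 for the list monocyte-derived and lipid-associated macrophage markers in diet effect in WT, 0.282 for the list interferon gamma response and antigen presentation in diet effect in WT and 0.0766 for the list hepatocyte markers in diet effect in WT. Without WT_chow replicate 4 it was 0.0923 for the list unfolded protein and integrated stress response in diet effect in WT. The interferon gamma and hepatocyte calls were also lost without WT_chow replicate 4 (0.19 and 0.0529), WT_HFD replicate 1 (0.132 and 0.0857) or WT_HFD replicate 3 (0.0556 and 0.0543). The hepatocyte call was lost without WT_HFD replicate 4 (0.0599), and the macrophage call without WT_HFD replicate 1 (0.0828) or 3 (0.0536).

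Camera did not call the other lists of the diet effect in WT. Of 27 xenobiotic metabolism genes 4 rose and 5 fell (camera adjusted p = 0.146), of 19 gluconeogenesis and insulin signalling genes 3 rose and 5 fell (0.404), and of 22 bile acid synthesis and transport genes 1 rose and 2 fell (0.387). Of 25 cholesterol synthesis genes 2 rose and 2 fell (0.667), of 32 acute phase genes 1 rose and 4 fell (0.708), and of 19 genes of inflammatory cytokines and chemokines 2 rose and 1 fell (0.483). Of 38 oxidative phosphorylation genes 1 fell (0.648). No member passed among 13 genes of the type 2 response and alternative macrophage activation (0.648), 15 Kupffer cell markers (0.667), 13 neutrophil markers (0.667), 8 erythroid markers (0.708) and 4 B and plasma cell markers (0.733). Of 16 T and NK cell markers 2 fell (0.178), of 14 cholangiocyte markers 1 fell (0.692), of 18 endothelial cell markers 3 rose and 3 fell (0.936), and of 4 adipocyte markers 3 rose (0.17). With 2 measured eosinophil and mast cell markers, neither passing, 1 pancreas marker, Cela1 (down by 1.17), and 0 muscle markers, those lists were too small for camera. Marker lists report RNA of a cell type, not cell numbers.

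The diet effect in WT comprised 2511 called genes, 1242 higher and 1269 lower, with 324 and 109 of them changed at least 2-fold. CPM did not overlap between the groups for 24.3% of tested genes, against 2.86% by chance.

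The diet effect in IL4KO asks the same of livers labelled as lacking IL-4. Fatty acid oxidation genes again rose: of 28 genes of fatty acid oxidation and PPARA targets, 10 rose and 0 fell, and 16 rose adjusted over the list alone (camera adjusted p = 1.23e-11; adjusted p = 0.484 with an estimated correlation). Vnn1 went from 57.2 ± 15.4 to 196 ± 9.9 CPM (FDR 0.00278), Cpt1a rose by 0.65 (SE 0.12) and the hormone gene Fgf21, a PPARA target, rose by 3.15 (SE 0.556), from 0.974 ± 0.252 CPM with n of 4 to 8.64 ± 2.73 CPM with n of 3. Of 21 lipid droplet and PPARG target genes, 12 rose and 0 fell, and 15 rose adjusted over the list alone (camera adjusted p = 8.02e-11; adjusted p = 0.484 with an estimated correlation). Of 24 lipogenesis genes 2 rose and 3 fell (camera adjusted p = 0.251). Fads2 was at 814 ± 60.4 against 382 ± 30.5 CPM, and Acly, which makes acetyl-CoA for lipogenesis, was lower at 295 ± 20.2 against 583 ± 131 CPM (FDR 0.00264). Of 27 xenobiotic metabolism genes 0 rose and 5 fell, and 3 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.00036; adjusted p = 0.545 with an estimated correlation). Cyp1a2 fell by 2.04 (SE 0.247, FDR 0.000108).

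Matrix genes rose in the diet effect in IL4KO. Of 42 genes of extracellular matrix and stellate cell activation, 20 rose and 0 fell, and 32 rose adjusted over the list alone (camera adjusted p = 1.62e-14; adjusted p = 0.484 with an estimated correlation). The mean list level (log2 CPM minus the mean of all libraries) was 0.172, 1.23 and -0.539 in IL4KO_HFD replicates 1, 2 and 3 against -0.712 to -0.372 on chow. Col3a1, a fibrillar collagen gene, was at 97.6 ± 95.3 against 16.6 ± 4.45 CPM (FDR 0.0086), and its call was lost without IL4KO_HFD replicate 2, as were those of Dcn, Trem2, Gpnmb, Cidea, Corin, Ly6d and Fabp4. Of 21 macrophage markers of the monocyte-derived and lipid-associated list 5 rose and 0 fell, and 8 rose adjusted over the list alone (camera adjusted p = 0.000138; adjusted p = 0.99 with an estimated correlation). Female-biased liver genes rose, 8 of 15 with 0 lower, and of 21 male-biased liver genes 2 fell and 0 rose (camera adjusted p = 4.98e-06 and 6.04e-08; adjusted p = 0.484 with an estimated correlation for each). Female-biased levels were 0.983, 1.43 and -0.643 in those 3 libraries against -1.11 to -0.357 on chow. Srgap3 fell, from 5.18 ± 0.643 to 0.269 ± 0.251 CPM (FDR 4.06e-06). For oxidative phosphorylation 0 of 38 genes passed although camera called the list (camera adjusted p = 0.0439; adjusted p = 0.999 with an estimated correlation).

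The diet effect in IL4KO comprised 1170 called genes, 662 higher and 508 lower, with no overlap of CPM for 19.6% of tested genes against 5.71% by chance. The count was 528 when only the compared groups were fitted, 712 without IL4KO_chow replicate 1, 733 without IL4KO_chow replicate 3, 236 without IL4KO_HFD replicate 2 and 2030 without IL4KO_HFD replicate 3. The call of the list monocyte-derived and lipid-associated macrophage markers in diet effect in IL4KO was lost without IL4KO_HFD replicate 2 (adjusted p = 0.788). That of the list oxidative phosphorylation in diet effect in IL4KO was lost without IL4KO_chow replicate 2 (0.0598), IL4KO_chow replicate 3 (0.237) or IL4KO_HFD replicate 1 (0.493).

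The diet effect in dKO asks what HFD changes in libraries labelled dKO. Genes of inflammation and of bile duct cells fell with the diet. All 13 of 13 neutrophil markers fell (camera adjusted p = 3.47e-06; adjusted p = 0.247 with an estimated correlation). The granule protease gene Elane was at 0.213 ± 0.295 against 5.83 ± 3.83 CPM (FDR 2.13e-05) and the receptor gene Csf3r at 2.17 ± 1.63 against 12.3 ± 2.33 CPM. Of 14 cholangiocyte markers 12 fell and 0 rose (camera adjusted p = 4.11e-05; adjusted p = 0.247 with an estimated correlation). Mmp7 was at 1.33 ± 1.43 against 17.2 ± 5.58 CPM (FDR 4.7e-06), and Epcam fell by 1.42 (SE 0.247). Of 32 acute phase genes 22 fell and 1 rose, and 25 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.84e-06; adjusted p = 0.308 with an estimated correlation). The haptoglobin gene Hp was at 5330 ± 2730 against 12800 ± 1330 CPM. Markers of Kupffer cells fell at 13 of 15 genes, those of monocyte-derived and lipid-associated macrophages at 16 of 21 and inflammatory cytokines and chemokines at 13 of 19, with 0 higher in each (camera adjusted p = 1.31e-06 to 2.06e-06; adjusted p = 0.247 to 0.308 with an estimated correlation). The lysozyme gene Lyz2 was at 40.2 ± 8.79 against 143 ± 17.6 CPM, Il1b was at 1.59 ± 1.18 against 6.71 ± 1.23 CPM, and the Kupffer cell gene Timd4 fell by 1.65 (SE 0.307). dKO_HFD replicate 4 stood apart in these groups, with a mean neutrophil list level of 2.1 log2 CPM above the mean of all libraries, against -1.27 to -1.08 in the other dKO_HFD libraries.

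Genes of fatty acid oxidation and oxidative phosphorylation rose in the diet effect in dKO. Of 28 genes of fatty acid oxidation and PPARA targets 25 rose and 0 fell, and 26 rose adjusted over the list alone (camera adjusted p = 3.51e-19; adjusted p = 0.247 with an estimated correlation). Ppara was at 471 ± 82.9 against 190 ± 42.6 CPM (FDR 5.13e-06) and the fatty acid binding protein gene Fabp1 at 4160 ± 1020 against 1710 ± 289 CPM. Of 38 oxidative phosphorylation genes 33 rose and 0 fell (camera adjusted p = 9.63e-14; adjusted p = 0.247 with an estimated correlation). Genes of lipid droplets and PPARG targets rose at 14 of 21, bile acid genes at 13 of 22 with 1 lower, and gluconeogenesis and insulin signalling genes at 11 of 19 (camera adjusted p = 3.47e-06, 3e-06 and 0.000508; adjusted p = 0.247 with an estimated correlation for each). dKO_HFD replicate 4 stood apart here too, with mean levels of -1.05 for lipid droplet genes and -0.399 for gluconeogenesis genes, inside the dKO_chow ranges of -1.36 to -0.967 and -0.659 to -0.318. Cholesterol synthesis genes fell at 17 of 25 with 0 higher (camera adjusted p = 2.15e-05; adjusted p = 0.379 with an estimated correlation). Lipogenesis genes rose at 6 of 24 and fell at 7 (camera adjusted p = 0.873). Clock genes rose at 12 of 19 and fell at 3 (camera adjusted p = 0.000654; adjusted p = 0.247 with an estimated correlation).

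Immune lists fell in the diet effect in dKO. Of 40 genes of the interferon gamma response and antigen presentation 28 fell and 0 rose, of 29 type I interferon genes 19 fell, of 16 T and NK cell markers 13 fell and 1 rose, and all 4 of 4 B and plasma cell markers fell (camera adjusted p = 4.49e-08, 4.37e-05, 2.75e-05 and 0.0171; adjusted p = 0.308, 0.312, 0.247 and 0.247 with an estimated correlation). Cell cycle genes fell at 14 of 28 with 2 higher, male-biased genes rose at 8 of 21, hepatocyte markers rose at 9 of 17 with 2 lower, xenobiotic metabolism genes rose at 10 of 27 with 2 lower, and type 2 response genes fell at 5 of 13 (camera adjusted p = 0.0118, 0.0138, 0.0138, 0.0154 and 0.0395; adjusted p = 0.402, 0.571, 0.332, 0.414 and 0.312 with an estimated correlation). Without dKO_HFD replicate 4 the adjusted p was 0.0641 for the list cell cycle in diet effect in dKO, 0.0641 for the list male-biased liver genes in diet effect in dKO and 0.0575 for the list hepatocyte markers in diet effect in dKO. The xenobiotic level was -1.09 in dKO_HFD replicate 4, below the -0.753 to -0.48 of dKO_chow. The adjusted p was 0.0559 without dKO_HFD replicate 3 for the list xenobiotic metabolism in diet effect in dKO. It was 0.0535 and 0.0661 without dKO_chow replicate 3 and dKO_HFD replicate 2 for the list type 2 response and alternative macrophage activation in diet effect in dKO.

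The diet effect in dKO comprised 5153 called genes, 2506 higher and 2647 lower, with 359 and 1081 of them changed at least 2-fold and no overlap of CPM for 31.6% of tested genes against 2.86% by chance. With upper quartile scaling the split was 1885 higher and 3340 lower.

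**Figure D3:**
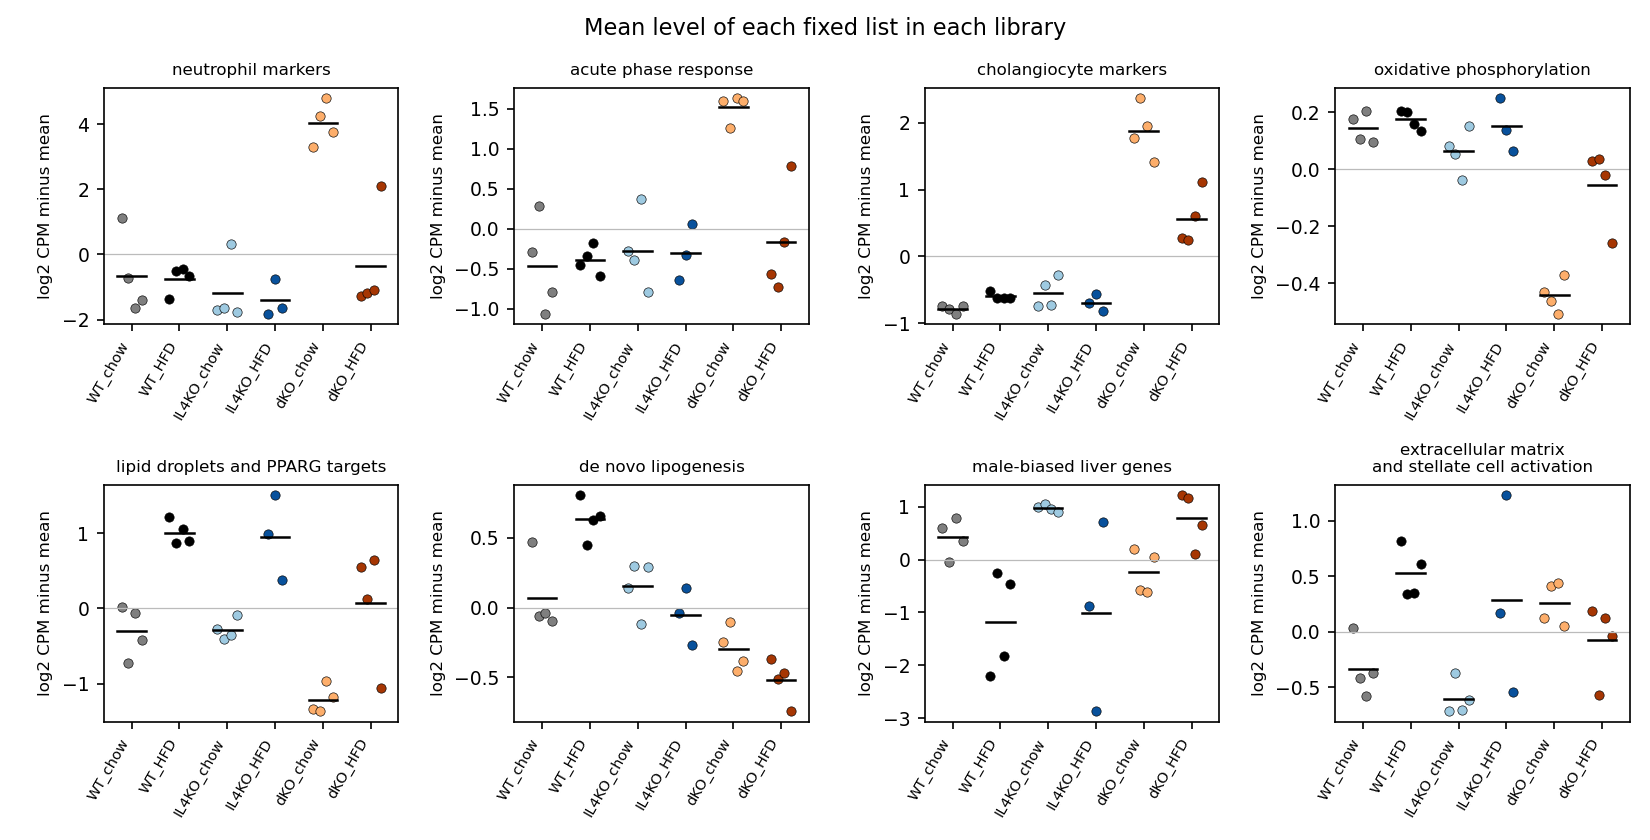
Mean level of 8 fixed gene lists in each library (vertical axis, log2 CPM minus the mean of all libraries; 1 point per mouse, bars at group means) for 6 groups along the horizontal axis. Neutrophil markers lie highest in dKO_chow, and dKO_HFD replicate 4 lies at 2.1 against -1.27 to -1.08 in the other dKO_HFD libraries.

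IL4KO against WT on chow asks what the labelled IL-4 deletion changes at baseline. Stress response and cholesterol genes were lower. Of 27 genes of the unfolded protein and integrated stress response 9 were lower and 0 higher, and 14 were lower adjusted over the list alone (camera adjusted p = 5.49e-06; adjusted p = 0.642 with an estimated correlation). The chaperone gene Dnajb9 was at 54.2 ± 2.56 against 134 ± 53.3 CPM (FDR 0.000283), and Herpud1, of endoplasmic reticulum degradation, at 672 ± 66.1 against 1150 ± 197 CPM. Of 25 cholesterol synthesis genes 6 were lower and 0 higher (camera adjusted p = 1.31e-05; adjusted p = 0.967 with an estimated correlation). Hmgcs1 was at 322 ± 17.8 against 647 ± 215 CPM (FDR 0.00664), and Sc5d was lower by 0.65 (SE 0.119). Of 19 clock genes 9 were higher and 2 lower (camera adjusted p = 6.06e-05; adjusted p = 0.207 with an estimated correlation). Of 4 adipocyte markers 2 were higher (camera adjusted p = 0.0031; adjusted p = 0.0762 with an estimated correlation), namely the glucose transporter gene Slc2a4 by 2.88 (SE 0.421) and the lipase gene Lipe by 0.84 (SE 0.126).

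Single genes also differed in IL4KO against WT on chow. The protease gene Ctse was at 0.254 ± 0.232 against 67.7 ± 6.03 CPM (FDR 8.18e-08), Ren1, which has a near-identical paralog in some strains, at 0.0458 ± 0.0529 against 31.4 ± 6.58 CPM, and Cyp2c39 at 2.5 ± 0.457 against 248 ± 39.9 CPM. Insc was higher by 3.51 (SE 0.202, FDR 1.07e-10), Sox13 by 2.43 (SE 0.206) and the steroidogenic Cyp17a1 by 3.11 (SE 0.507). The comparison had 1239 called genes, 764 higher and 475 lower, and no overlap of CPM for 18.5% of tested genes against 2.86% by chance. No camera call was made for macrophage, Kupffer cell, neutrophil or T and NK cell markers (camera adjusted p = 0.346, 0.123, 0.21 and 0.0836), where 0 genes passed by edgeR (3148 of all tested genes had an unadjusted p below 0.05).

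IL4KO against WT on HFD asks the same on the fatty diet. Lipogenesis and cholesterol synthesis genes were lower. Of 24 lipogenesis genes 5 were lower and 0 higher, and 9 were lower adjusted over the list alone (camera adjusted p = 7.74e-11; adjusted p = 0.128 with an estimated correlation). Acly was at 295 ± 20.2 CPM with n of 3 against 663 ± 111 CPM with n of 4 (FDR 0.000721), Gpam at 132 ± 3.4 against 262 ± 47.9 CPM, and the fatty acid synthase gene Fasn at 646 ± 195 against 1670 ± 339 CPM, a call lost without dKO_HFD replicate 4 and IL4KO_HFD replicate 3. Of 25 cholesterol synthesis genes 5 were lower and 0 higher, and 8 were lower adjusted over the list alone (camera adjusted p = 4.92e-10; adjusted p = 0.984 with an estimated correlation). Sc5d was lower by 0.91 (SE 0.131, FDR 0.000229) and Insig1 by 1.29 (SE 0.225, FDR 0.00244). For the interferon gamma list 0 of 40 genes passed, and for the type I interferon response 1 was higher and 1 lower of 29, with medians of -0.19 and -0.31 (camera adjusted p = 3.77e-05 and 0.00056; adjusted p = 0.984 with an estimated correlation for each). Cyp17a1 was higher by 4.65 (SE 0.46). Ctse was at 1 ± 0.522 against 239 ± 51.5 CPM.

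IL4KO against WT on HFD had 389 called genes, 223 higher and 166 lower, and no overlap of CPM for 13.6% of tested genes against 5.71% by chance. The count was 95 when only the compared groups were fitted, 227 without WT_HFD replicate 2, 186 without WT_HFD replicate 4, 185 without IL4KO_HFD replicate 1, 631 without IL4KO_HFD replicate 2 and 227 without IL4KO_HFD replicate 3. The list NRF2 targets in IL4KO against WT on HFD, with 0 of 21 genes passing, was called (camera adjusted p = 0.0131; adjusted p = 0.984 with an estimated correlation) but not without IL4KO_HFD replicate 3 (adjusted p = 0.676). The list T and NK cell markers in IL4KO against WT on HFD, with 0 of 16 passing, was called (camera adjusted p = 0.0268; adjusted p = 0.984 with an estimated correlation) but not without IL4KO_HFD replicate 1 (adjusted p = 0.148) or IL4KO_HFD replicate 3 (0.11).

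Genes called between IL4KO and WT gathered on chromosomes 1 and 19 (mm10). Within 10 Mb of Il10, at 131019845 to 131024974 on chromosome 1, 27 of 100 tested genes were called on chow (Fisher's exact odds ratio 3.54, adjusted p = 5.82e-06) and 14 of 100 on HFD (5.39, adjusted p = 1.03e-05), although the label of these mice names only IL-4. Within 10 Mb of Il4 on chromosome 11 the odds ratio over 181 genes was 1.08 to 1.9 in the genotype comparisons, and none passed (adjusted p = 0.146 to 0.652). In dKO against IL4KO 57 of 100 genes near Il10 were called on chow (1.62, adjusted p = 0.048) and 12 of 100 on HFD (5.51, adjusted p = 2.73e-05), and in dKO against WT 53 of 100 on chow (1.31, adjusted p = 0.286) and 36 of 100 on HFD (1.74, adjusted p = 0.0296). A scan of 273 bins of 10 Mb, chosen after seeing the data, gave chromosome 19 from 40 to 50 Mb, with 30 of 100 genes called in IL4KO against WT on chow (Fisher's exact adjusted p = 2.2e-06) and 15 of 100 on HFD (8.03e-05), and chromosome 1 from 130 to 140 Mb, with 25 of 82 (1.35e-05) and 13 of 82 (0.00013). On HFD chromosome 19 from 50 to 60 Mb also passed in IL4KO against WT, with 6 of 33 (0.0368), and chromosome 19 from 40 to 50 Mb in dKO against WT, with 46 of 100 (0.000584). In dKO against IL4KO on HFD chromosome 1 passed from 120 to 130 Mb, with 5 of 22, and from 130 to 140 Mb, with 9 of 82 (0.0273 for each). Ctse, Ren1, Sox13 and Ppfia4 lie in the chromosome 1 bin, Cyp17a1 and Sfxn2 in the chromosome 19 bin.

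**Figure D4:**
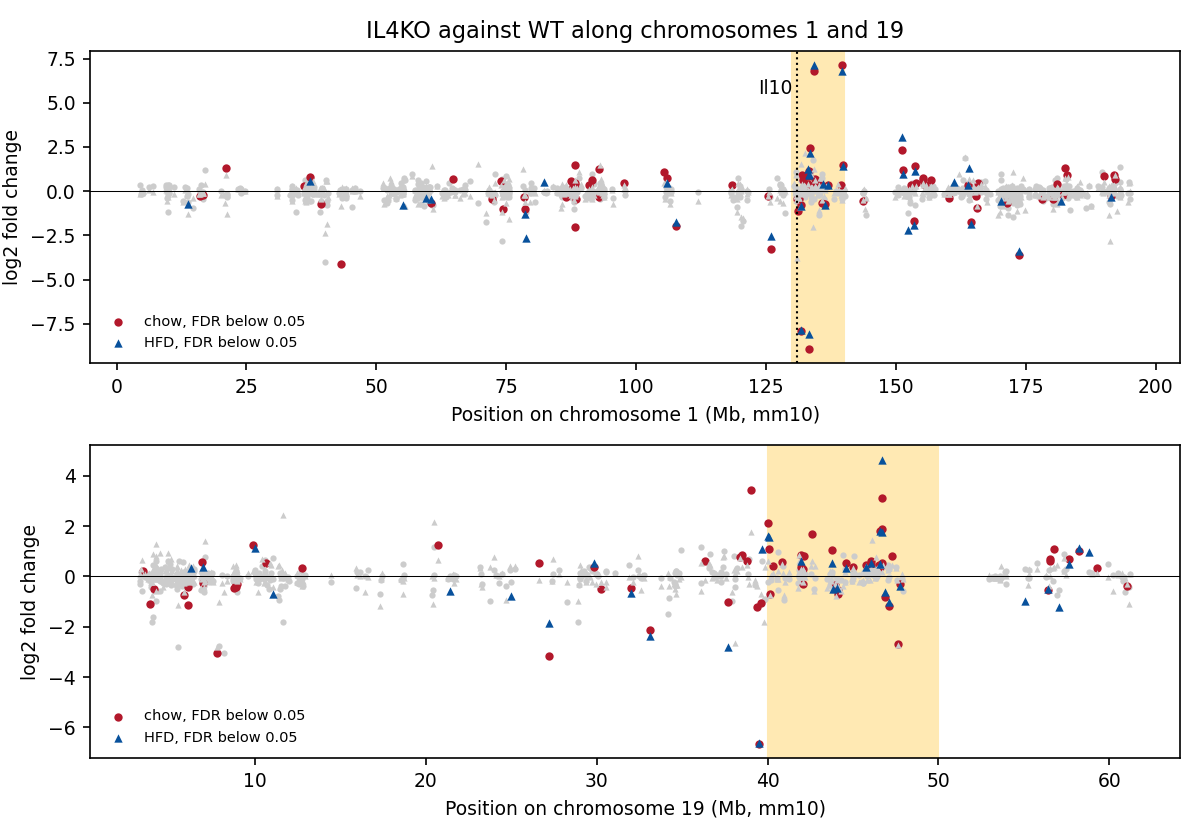
Log2 fold change of IL4KO against WT (vertical axis) along chromosomes 1 and 19 (horizontal axis, Mb, mm10), 1 point per tested gene and diet, with red circles for chow and blue triangles for HFD at FDR below 0.05 and grey for other genes. The shaded bins held 25 of 82 called genes on chromosome 1 and 30 of 100 on chromosome 19 on chow.

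dKO against WT on chow asks what the labelled double deletion changes at baseline. Genes of neutrophils, bile duct cells and the acute phase were higher. All 13 of 13 neutrophil markers were higher, with a median of 4.76 (camera adjusted p = 2.41e-05; adjusted p = 0.4 with an estimated correlation), and the lactoferrin gene Ltf was at 28.7 ± 19.3 against 0.482 ± 0.851 CPM (FDR 0.00034). Of 14 cholangiocyte markers 13 were higher and 0 lower (camera adjusted p = 6e-11; adjusted p = 0.116 with an estimated correlation). Epcam was at 9.55 ± 2.95 against 0.893 ± 0.525 CPM and Mmp7 at 17.2 ± 5.58 against 0.0915 ± 0.106 CPM. Of 32 acute phase genes 26 were higher and 2 lower (camera adjusted p = 2.07e-07; adjusted p = 0.4 with an estimated correlation). Hp was at 12800 ± 1330 against 3600 ± 1380 CPM (FDR 3.02e-05). Among 21 monocyte-derived and lipid-associated macrophage markers 17 were higher, among 15 Kupffer cell markers 13 higher and 1 lower, and among 19 cytokine genes 14 higher and 1 lower (camera adjusted p = 1.77e-06, 0.000275 and 2.11e-05; adjusted p = 0.4 with an estimated correlation for each). Spp1, which encodes osteopontin, was at 624 ± 164 against 39.7 ± 3.18 CPM. Of 40 interferon gamma genes 24 were higher, of 16 T and NK cell markers 12 were higher and 1 lower, and of 42 matrix genes 15 were higher and 1 lower (camera adjusted p = 2.11e-05, 0.00575 and 0.00575; adjusted p = 0.422, 0.4 and 0.605 with an estimated correlation).

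Mitochondrial and other metabolic genes were lower in dKO against WT on chow. All 38 of 38 oxidative phosphorylation genes were lower, with a median of -0.58 (camera adjusted p = 4.47e-25; adjusted p = 0.149 with an estimated correlation), and Ndufb8 was at 61.5 ± 2.1 against 116 ± 10.6 CPM (FDR 1.9e-07). Of 28 genes of fatty acid oxidation and PPARA targets 23 were lower and 0 higher (camera adjusted p = 3.25e-10; adjusted p = 0.393 with an estimated correlation). Bile acid genes were lower at 18 of 22 with 1 higher, xenobiotic metabolism genes at 17 of 27 with 1 higher, and gluconeogenesis and insulin signalling genes at 12 of 19 (camera adjusted p = 4.63e-08, 1.62e-06 and 8.66e-06; adjusted p = 0.149, 0.257 and 0.149 with an estimated correlation). Lipid droplet genes were lower at 9 of 21, lipogenesis genes at 12 of 24 with 2 higher, hepatocyte markers at 9 of 17 with 2 higher and stress response genes at 12 of 27 with 2 higher (camera adjusted p = 0.00149, 0.00343, 0.00119 and 0.00145; adjusted p = 0.422, 0.4, 0.393 and 0.405 with an estimated correlation). Trhde was at least 104-fold lower, and Ppfia4 at least 49.7-fold higher (floor of 3 counts over the group at 0).

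dKO against WT on chow had 5966 called genes, 3148 higher and 2818 lower, of which 1391 and 365 changed at least 2-fold, and no overlap of CPM for 43.9% of tested genes against 2.86% by chance. With upper quartile scaling the split was 3748 higher and 2183 lower. The list NRF2 targets in dKO against WT on chow had 8 of 21 genes lower and 1 higher (camera adjusted p = 0.0328; adjusted p = 0.476 with an estimated correlation; adjusted p = 0.0631 without WT_chow replicate 1). The list type 2 response and alternative macrophage activation in dKO against WT on chow had 7 of 13 genes higher and 1 lower (camera adjusted p = 0.035; adjusted p = 0.4 with an estimated correlation; adjusted p = 0.0534 without WT_chow replicate 3). The list type I interferon response in dKO against WT on chow had 8 of 29 genes higher and 1 lower (camera adjusted p = 0.0398; adjusted p = 0.605 with an estimated correlation). Its call was lost without WT_chow replicate 3 (adjusted p = 0.153), WT_chow replicate 4 (0.0902) or dKO_chow replicate 3 (0.0747).

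dKO against WT on HFD asks the same on the fatty diet. Lipogenesis genes were lower: of 24 genes 18 were lower and 0 higher, with the same counts adjusted over the list alone (camera adjusted p = 6.57e-17), and this call held with an estimated correlation (adjusted p = 0.0239 with an estimated correlation). Fasn was at 372 ± 51.1 against 1670 ± 339 CPM (FDR 9.1e-06) and Acly at 229 ± 28.7 against 663 ± 111 CPM. Of 21 NRF2 targets 17 were lower and 1 higher (camera adjusted p = 1.09e-10; adjusted p = 0.136 with an estimated correlation). Gclc, of glutathione synthesis, was at 158 ± 36 against 361 ± 54.1 CPM, and Nqo1 was lower by 1.60 (SE 0.261). Of 28 cell cycle genes 12 were lower and 0 higher (camera adjusted p = 1.85e-06; adjusted p = 0.355 with an estimated correlation). Lipid droplet genes were lower at 9 of 21 with 1 higher, matrix genes at 9 of 42, type I interferon genes at 13 of 29 with 1 higher, interferon gamma genes at 10 of 40 with 1 higher, and oxidative phosphorylation genes at 16 of 38 (camera adjusted p = 0.000281, 2e-04, 1.74e-06, 0.00339 and 1.31e-07; adjusted p = 0.63, 0.947, 0.63, 0.947 and 0.63 with an estimated correlation).

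Bile duct and male-biased genes were higher in dKO against WT on HFD. Of 14 cholangiocyte markers 9 were higher and 0 lower (camera adjusted p = 1.2e-05; adjusted p = 0.269 with an estimated correlation). Epcam was at 3.62 ± 0.721 against 1.16 ± 0.205 CPM (FDR 0.000565). Of 21 male-biased genes 12 were higher and 0 lower (camera adjusted p = 1.02e-05; adjusted p = 0.63 with an estimated correlation). Elovl3 was at 262 ± 82.6 against 68 ± 22.6 CPM. No neutrophil marker of 13 passed, with a median of 1.63 (camera adjusted p = 0.544). Their mean level (log2 CPM minus the mean of all libraries) was 2.1 in dKO_HFD replicate 4, -1.27 to -1.08 in the other dKO_HFD libraries and -1.36 to -0.456 in WT_HFD. The comparison had 3157 called genes, 1662 higher and 1495 lower, and no overlap of CPM for 25% of tested genes against 2.86% by chance. The list female-biased liver genes in dKO against WT on HFD was lower at 7 of 15 with 2 higher (camera adjusted p = 0.0122; adjusted p = 0.76 with an estimated correlation), and the call was lost without dKO_HFD replicate 4 (adjusted p = 0.0653).

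dKO against IL4KO on chow compares the labelled genotypes that share the IL-4 deletion. Genes of inflammation, bile duct cells and cholesterol synthesis were higher. Of 25 cholesterol synthesis genes 20 were higher and 0 lower (camera adjusted p = 2.97e-06; adjusted p = 0.319 with an estimated correlation). Hmgcs1 was at 860 ± 244 against 322 ± 17.8 CPM (FDR 5.32e-05). All 13 of 13 neutrophil markers were higher, Kupffer cell markers at 14 of 15 with 1 lower, macrophage markers of the monocyte-derived list at 16 of 21, cytokine genes at 16 of 19, acute phase genes at 27 of 32 with 2 lower and T and NK cell markers at 13 of 16 with 1 lower (camera adjusted p = 7.6e-08 to 0.000115; adjusted p = 0.234 with an estimated correlation for each). Spp1 was at 624 ± 164 against 32.7 ± 2.75 CPM, Csf3r was higher by 3.22 (SE 0.366), and Ctsg, a granule protease gene, at least 30.8-fold higher. Cholangiocyte markers were higher at 12 of 14 with 1 lower, matrix genes at 22 of 42 and interferon gamma genes at 23 of 40 with 2 lower (camera adjusted p = 2.11e-09, 4.41e-05 and 2.28e-05; adjusted p = 0.184, 0.407 and 0.385 with an estimated correlation). Epcam was higher by 3.90 (SE 0.335).

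Lower groups in dKO against IL4KO on chow were oxidative phosphorylation at 34 of 38, fatty acid oxidation and PPARA targets at 23 of 28 with 1 higher, xenobiotic metabolism at 20 of 27 and bile acid genes at 18 of 22 (camera adjusted p = 7.71e-18, 6.75e-10, 2.11e-09 and 7.44e-08; adjusted p = 0.234, 0.234, 0.216 and 0.216 with an estimated correlation). Lipogenesis genes were lower at 14 of 24 with 2 higher, lipid droplet genes at 11 of 21 with 1 higher, gluconeogenesis genes at 10 of 19 with 1 higher, clock genes at 10 of 19 with 3 higher, hepatocyte markers at 10 of 17 with 2 higher and male-biased genes at 9 of 21 (camera adjusted p = 0.000648, 0.000767, 0.000176, 0.000546, 0.00913 and 0.0104; adjusted p = 0.234, 0.334, 0.234, 0.234, 0.311 and 0.509 with an estimated correlation). The comparison had 5822 called genes, 2960 higher and 2862 lower, or 3667 higher and 2092 lower with upper quartile scaling, and no overlap of CPM for 45.8% of tested genes against 2.86% by chance. The list endothelial cell markers in dKO against IL4KO on chow was lower at 8 of 18 with 1 higher (camera adjusted p = 0.0235; adjusted p = 0.385 with an estimated correlation; adjusted p = 0.0714 without dKO_chow replicate 1). The list type I interferon response in dKO against IL4KO on chow was higher at 13 of 29 genes with 2 lower (camera adjusted p = 0.0344; adjusted p = 0.568 with an estimated correlation). It was not called without IL4KO_chow replicate 2 (adjusted p = 0.0734) or dKO_chow replicate 3 (0.0691).

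dKO against IL4KO on HFD asks the same on the fatty diet. Camera called NRF2 targets and lipid genes lower. Of 21 NRF2 targets 8 were lower and 0 higher, of 24 lipogenesis genes 4 lower, of 21 lipid droplet genes 4 lower and of 38 oxidative phosphorylation genes 2 lower, or 14, 8, 7 and 20 lower adjusted over the list alone (camera adjusted p = 5.36e-10, 1.26e-07, 1.31e-08 and 8.31e-11; adjusted p = 0.182, 0.182, 0.303 and 0.411 with an estimated correlation). Libraries overlapped, since IL4KO_HFD replicate 3 lay at -0.345 for NRF2 targets (dKO_HFD -0.5 to -0.216) and at 0.374 for lipid droplet genes, below dKO_HFD replicates 1 and 3 (0.555 and 0.641), with dKO_HFD replicate 4 at -1.05. Of 14 cholangiocyte markers 4 were higher and 0 lower, and 11 were higher adjusted over the list alone (camera adjusted p = 6.04e-09; adjusted p = 0.16 with an estimated correlation). For male-biased genes and for PPARA targets 0 genes passed, with medians of 0.92 and -0.28 (camera adjusted p = 2.77e-08 and 1.56e-05; adjusted p = 0.403 and 0.681 with an estimated correlation). Male-biased levels overlapped as well, at -0.885, -2.86 and 0.707 in IL4KO_HFD replicates 1 to 3 against 0.0987 to 1.21 in dKO_HFD. Lamc3, a laminin chain gene, was at 10.6 ± 2.41 CPM with n of 4 against 1.7 ± 0.277 CPM with n of 3 (FDR 1.8e-06). Ctse was at 94 ± 49.5 against 1 ± 0.522 CPM, and Ren1 at 25.6 ± 19.1 against 0.0831 ± 0.0727 CPM. The call of Ctse was lost when only the compared groups were fitted.

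dKO against IL4KO on HFD had 323 called genes, 122 higher and 201 lower, with no overlap of CPM for 11.4% of tested genes against 5.71% by chance. The split was 146 higher and 121 lower with the deposited log2 values. The count was 571 with DESeq2, 207 with limma-voom, 4 when only the compared groups were fitted, 93 without IL4KO_HFD replicate 1, 39 without IL4KO_HFD replicate 2, 1241 without IL4KO_HFD replicate 3, 106 without dKO_HFD replicate 2 and 118 without dKO_HFD replicate 4. The list extracellular matrix and stellate cell activation in dKO against IL4KO on HFD was called lower (camera adjusted p = 1.96e-05; adjusted p = 0.732 with an estimated correlation). Without IL4KO_HFD replicate 2 its direction turned (adjusted p = 0.765). The same library turned the direction of the list monocyte-derived and lipid-associated macrophage markers in dKO against IL4KO on HFD, from lower (camera adjusted p = 0.0156; adjusted p = 0.752 with an estimated correlation) to higher (adjusted p = 0.039 without it), and dKO_HFD replicates 2 and 3 ended that call (0.231 and 0.0533).

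Further calls in dKO against IL4KO on HFD each hung on single libraries. The list cell cycle in dKO against IL4KO on HFD was lower (camera adjusted p = 2.36e-05; adjusted p = 0.403 with an estimated correlation; 0.0957 without IL4KO_HFD replicate 2). The list cholesterol synthesis in dKO against IL4KO on HFD was called higher with 0 genes passing (camera adjusted p = 0.0018; adjusted p = 0.752 with an estimated correlation; 0.459 without IL4KO_HFD replicate 2 and 0.0846 without dKO_HFD replicate 2). For the list xenobiotic metabolism in dKO against IL4KO on HFD, 4 of 27 genes were lower and 1 higher (camera adjusted p = 0.00554; adjusted p = 0.64 with an estimated correlation; 0.244 without IL4KO_HFD replicate 1 and 0.302 without dKO_HFD replicate 4). The list type I interferon response in dKO against IL4KO on HFD was lower (camera adjusted p = 0.00554; adjusted p = 0.752 with an estimated correlation; 0.301 without IL4KO_HFD replicate 2, 0.0712 without dKO_HFD replicate 2 and 0.0533 without dKO_HFD replicate 3). The list T and NK cell markers in dKO against IL4KO on HFD was higher (camera adjusted p = 0.00554; adjusted p = 0.64 with an estimated correlation; 0.0537 without IL4KO_HFD replicate 1, 0.0929 without IL4KO_HFD replicate 3 and 0.113 without dKO_HFD replicate 4). The list neutrophil markers in dKO against IL4KO on HFD was called higher with 0 genes passing (camera adjusted p = 0.021; adjusted p = 0.752 with an estimated correlation; 0.0891 without IL4KO_HFD replicate 1, 0.129 without IL4KO_HFD replicate 3 and 0.516 without dKO_HFD replicate 4). The list endothelial cell markers in dKO against IL4KO on HFD was lower (camera adjusted p = 0.036; adjusted p = 0.732 with an estimated correlation; 0.0598 without IL4KO_HFD replicate 1, 0.41 without IL4KO_HFD replicate 2, 0.112 without dKO_HFD replicate 2 and 0.0533 without dKO_HFD replicate 3).

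The interaction IL4KO minus WT asks whether the diet effect differs between these genotypes. Camera called 7 lists, among them lipogenesis and the circadian clock. Of 24 lipogenesis genes 1 was lower and 0 higher, and 8 were lower adjusted over the list alone, with a median of -0.72 (camera adjusted p = 2.14e-12; adjusted p = 0.0488 with an estimated correlation). Gpam had a log2 interaction of -1.29 (SE 0.212, FDR 0.0147). Clock genes had 0 of 19 passing but 2 higher and 11 lower adjusted over the list alone (camera adjusted p = 2.08e-06; adjusted p = 0.0488 with an estimated correlation). Cell cycle, with a median of -0.56, and the interferon gamma list, with -0.35, had 0 genes passing (camera adjusted p = 1.76e-05 and 0.000112; adjusted p = 0.422 and 0.981 with an estimated correlation). Only 6 genes were called, with 1379 at an unadjusted p below 0.05.

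The 6 calls of the diet by genotype IL4KO minus WT interaction became 66 with DESeq2, 14 with the deposited log2 values (3 higher and 11 lower), 21 when only the compared groups were fitted, and 3 without WT_chow replicate 2, WT_chow replicate 4, IL4KO_chow replicate 2, IL4KO_HFD replicate 2 or IL4KO_HFD replicate 3. The Gpam call was lost without WT_chow replicate 4 or any 1 of the 3 IL4KO_HFD libraries. The list unfolded protein and integrated stress response in diet by genotype IL4KO minus WT pointed up (camera adjusted p = 0.00115; adjusted p = 0.981 with an estimated correlation; 0.0662 without WT_chow replicate 4 and 0.12 without IL4KO_HFD replicate 3). The list type I interferon response in diet by genotype IL4KO minus WT pointed down (camera adjusted p = 0.00234; adjusted p = 0.981 with an estimated correlation; 0.0859 without WT_chow replicate 3, 0.0511 without WT_HFD replicate 1 and 0.0803 without IL4KO_HFD replicate 3). The list adipocyte markers in diet by genotype IL4KO minus WT pointed down (camera adjusted p = 0.006; adjusted p = 0.0488 with an estimated correlation; 0.0517 without IL4KO_HFD replicate 2).

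The interaction dKO minus WT asks the same of dKO and WT. Of 21 monocyte-derived and lipid-associated macrophage markers 17 were lower and 0 higher, of 40 interferon gamma genes 27 were lower, of 28 cell cycle genes 17 lower and 1 higher, and of 42 matrix genes 23 lower (camera adjusted p = 2.91e-10, 2.56e-11, 2.91e-10 and 3.03e-09; adjusted p = 0.251, 0.251, 0.251 and 0.261 with an estimated correlation). Of 38 oxidative phosphorylation genes 25 were higher and 0 lower, of 28 PPARA targets 17 higher, of 22 bile acid genes 15 higher and of 21 male-biased genes 12 higher (camera adjusted p = 2.91e-10, 6.33e-07, 2.85e-07 and 1.03e-07; adjusted p = 0.251, 0.287, 0.251 and 0.251 with an estimated correlation). Lipogenesis genes were lower at 9 of 24 with 2 higher, and Kupffer cell markers at 11 of 15 (camera adjusted p = 0.000504 and 1.31e-05; adjusted p = 0.251 with an estimated correlation for each). Aadat, of kynurenine and lysine breakdown, had an interaction of 1.36 (SE 0.194, FDR 0.000532) and the kinase gene Pkmyt1 one of -3.67 (SE 0.384). The interaction called 3254 genes, 1624 higher and 1630 lower, or 1135 higher and 1832 lower with upper quartile scaling, and 2130 without dKO_HFD replicate 2.

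In the diet by genotype dKO minus WT interaction 25 lists were called. Among those that hung on single libraries were the downward calls of the list T and NK cell markers in diet by genotype dKO minus WT (camera adjusted p = 0.0235; adjusted p = 0.394 with an estimated correlation; 0.0528 without dKO_HFD replicate 1) and the list B and plasma cell markers in diet by genotype dKO minus WT (camera adjusted p = 0.0129; adjusted p = 0.251 with an estimated correlation; 0.0634 without WT_HFD replicate 2 and 0.0512 without dKO_chow replicate 3). So was that of the list female-biased liver genes in diet by genotype dKO minus WT (camera adjusted p = 0.0376; adjusted p = 0.436 with an estimated correlation; 0.0516 without WT_HFD replicate 1, 0.0714 without WT_HFD replicate 3, 0.0578 without dKO_chow replicate 2, 0.0553 without dKO_chow replicate 3 and 0.164 without dKO_HFD replicate 4).

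The interaction dKO minus IL4KO compares the diet effects of the labelled knockouts. Of 21 monocyte-derived and lipid-associated macrophage markers 18 were lower and 0 higher, and of 42 matrix genes 25 were lower (camera adjusted p = 9.21e-12 and 3.1e-10; adjusted p = 0.347 and 0.378 with an estimated correlation). Oxidative phosphorylation genes were higher at 20 of 38, bile acid genes at 15 of 22 with 1 lower and clock genes at 9 of 19 with 3 lower (camera adjusted p = 1.07e-06, 4.3e-07 and 0.000457; adjusted p = 0.411, 0.347 and 0.347 with an estimated correlation). Car3, a carbonic anhydrase gene, had an interaction of 3.99 (SE 0.446, FDR 0.000164) and Tnfaip3, an NF-kB inhibitor, one of -1.96 (SE 0.27). The interaction called 3144 genes, 1636 higher and 1508 lower, or 1157 higher and 1887 lower with upper quartile scaling, and 1293 without IL4KO_HFD replicate 2. The call of the list cholesterol synthesis in diet by genotype dKO minus IL4KO was lost without IL4KO_HFD replicate 3 (adjusted p = 0.131), and that of the list cholangiocyte markers in diet by genotype dKO minus IL4KO without IL4KO_HFD replicate 2 (0.0536).

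Diet effects were also compared across all 12891 genes, which are not independent replicates. WT and IL4KO had a Pearson's r of 0.619 (Spearman's rho 0.529), with 387 genes higher in both against 63.8 by chance and 244 lower in both against 50. That r was 0.41 without IL4KO_HFD replicate 2. WT and dKO had an r of 0.129 (rho 0.119), or 0.243 (rho 0.323) over genes above the median level, with 516 genes higher in both against 241 by chance and 346 lower in both against 261. It was 0.0489 without WT_chow replicate 1, 0.0734 without WT_chow replicate 2 and 0.0724 without dKO_HFD replicate 3. IL4KO and dKO had an r of 0.00455 (rho -0.0295), or 0.154 (rho 0.155) over genes above the median level, with 238 higher in both against 129 and 126 lower in both against 104. That r ran from -0.0657 without IL4KO_HFD replicate 3 to 0.265 without IL4KO_HFD replicate 2. The diet effects share no library.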

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

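Tests of library depth, hepatocyte share, blood and label swap, the clustering on chromosomes, and the splits of the pairs were chosen only after the results were seen, while the mixture, gene copy and interaction split tests were written before. On component 1 dKO_HFD replicate 4 lay at -43.1 (other dKO_HFD libraries 10.2 to 17.2). Libraries far from the others of their group were sought in groups of 4, so not in IL4KO_HFD. By chance the test flags 1 of 20 pairs of measure and group (13 of 185 flagged, 9.25 by chance). Mean list levels gave 12 cases. In WT_chow these were lipogenesis in replicate 1 (0.47, others -0.0987 to -0.0388), Kupffer cell markers in replicate 3 (-0.626, others 0.118 to 0.205) and erythroid markers in replicate 4 (0.535, others -0.824 to -0.637). In WT_HFD they were cytokines (0.209, others -0.154 to -0.105), T and NK cell markers (-0.118, others -0.307 to -0.283) and cholangiocyte markers (-0.513, others -0.63 to -0.62) in replicate 1, NRF2 targets in replicate 2 (0.116, others 0.488 to 0.536) and Kupffer cell markers in replicate 4 (-0.252, others -0.0804 to -0.0585). They were neutrophil markers in IL4KO_chow replicate 3 (0.333, others -1.76 to -1.64), acute phase genes in dKO_chow replicate 2 (1.26, others 1.59 to 1.63), and B and plasma cell markers (0.379, others -0.701 to -0.635) and neutrophil markers (2.1, others -1.27 to -1.08) in dKO_HFD replicate 4. Among named genes 127 of 1932 pairs of gene and group had 1 library far from the other 3, against 96.6 by chance, and 37 of the 127 were in dKO_HFD replicate 4.

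The diet effect differed between genotypes at 6 genes and 7 lists for IL4KO minus WT, 3254 genes and 25 lists for dKO minus WT, and 3144 genes and 20 lists for dKO minus IL4KO. Of 100 drawn splits of the libraries, the real one included, 4, 3 and 3 gave as many calls, and the highest other counts were 1055, 5959 and 3928. The other splits with as many calls exchanged genotype in all or most libraries of 1 diet, which compares the genotypes themselves, so the highest counts do not measure chance for an interaction. For the pairs all 35 splits were run, and the real one alone gave its count (1 of 35) in every pair except dKO against IL4KO on HFD, where 2 of 35 did (323 real, 367 highest other) and chance could not be excluded. The highest other counts were 3 for the diet effect in WT, 22 in IL4KO and 2528 in dKO, 2 for IL4KO against WT on chow and 41 on HFD, 2 for dKO against WT on chow and 62 on HFD, and 2 for dKO against IL4KO on chow. The split with 2528 calls exchanged dKO_HFD replicate 4, which points to a structure of those samples.

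Higher neutrophil, acute phase and bile duct genes in dKO_chow were tested against 3 technical explanations, all chosen only after the result was seen. Greater depth is unlikely to account for it, since after thinning (4895 genes called, 4739 of them among the 5966) calls in the same direction were made for the list neutrophil markers in dKO against WT on chow (adjusted p = 1.6e-05), the list acute phase response in dKO against WT on chow (1.06e-08) and the list cholangiocyte markers in dKO against WT on chow (4.17e-11). Less hepatocyte RNA would raise other cell types alike. Instead the cholangiocyte median exceeded the endothelial one by 3.56 (SE 0.496 over genes, not mice, as below). The erythroid median was 0.757 (SE 0.205) and the neutrophil one 4.76 (SE 0.213). This cannot exclude blood left in the liver if its neutrophils rose. An inflamed liver in mice lacking these cytokines may account for it, which is untested here and stands beside an Il10 level against the label.

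The place of dKO_HFD replicate 4 between dKO_chow and the other dKO_HFD libraries was tested for a swap, chosen only after the result was seen, and for a mixture, written before. A swap with a dKO_chow library is unlikely, since the dKO_chow scores reached no higher than -64.64. A mixture with dKO_chow RNA is unlikely, since genes higher in dKO_chow gave a share of 45.4% (SE 0.943) and genes lower in it 78.3% (SE 1.71), a difference of 32.9 points. A mouse that responded less to the diet could account for it, which was not tested.

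The clusters of calls between IL4KO and WT on chromosomes 1 and 19 were tested for linked DNA of another strain, chosen only after the result was seen, and for gene copies, written before. Of genes called there on chow, 52 of 55 kept their direction on HFD (94.5%, elsewhere 83.7% of 1180, Fisher's exact p = 0.0352). Any genotype effect could do so, so linked DNA stays open. WT diet calls did not gather there (odds ratio 1.02, Fisher's exact p = 0.925). Reads shared between gene copies are unlikely to account for it, since without gene families 49 of 169 genes were still called (Fisher's exact p = 1e-12). Regulation by IL-4 stays open, but dKO, labelled as lacking it too, followed IL4KO only in part. Against WT on chow Sox13 differed by 2.43 in IL4KO and 2.36 in dKO and Sfxn2 by 1.82 and 1.43. Ctse differed by -7.89 and -1.56, Ren1 by -8.93 and -1.33 and Etnk2 by 1.14 and -0.983. On HFD Etnk2 had 0.907 and 0.357 and Ren1 -8.1 and 0.102.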

How the results depend on the processing

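Of 845 named gene results, 760 of them called, 843 kept their side and direction with RLE factors, 843 without robust estimation, 836 with upper quartile factors and 819 without a filter. The number was 793 with the deposited log2 values, 790 with limma-voom and 793 without dKO_HFD replicate 4 and IL4KO_HFD replicate 3. It was 833 of 836 with a strict filter, 819 of 844 with DESeq2, 803 of 832 after thinning and 705 of 809 when only the compared groups were fitted. Leaving out each library in turn kept 6288 of 6793, lost 462 and gained 43. Il10 in diet by genotype dKO minus IL4KO, not called, reversed from 1.26 to -1.04 with the deposited log2 values, where it rests on 0 to 2 counts in IL4KO, and the cause was not tested. No paired analysis was possible because the labels give no replicate numbers that tie a mouse of one group to a mouse of another. Where only the compared groups were fitted, which also changes the genes tested, the count of called genes in diet effect in IL4KO moved from 1170 to 528, and in IL4KO against WT on HFD from 389 to 95. It moved in dKO against IL4KO on HFD from 323 to 4, and in diet by genotype IL4KO minus WT from 6 to 21. Without dKO_HFD replicate 4 and IL4KO_HFD replicate 3 it moved to 2413 in diet effect in IL4KO. In dKO against IL4KO on HFD it moved to 1116 without them, 571 with DESeq2, 207 with limma-voom and 200 after thinning, with fewer counts. In diet by genotype IL4KO minus WT it moved to 18 without them, 66 with DESeq2 and 14 with the deposited log2 values. Apart from thinning no cause was tested. The main fit gives a gene 1 spread for all groups. Replicate r went down to 0.9504 in IL4KO_HFD and 0.9632 in dKO_HFD (others at least 0.9809). Main calls with IL4KO_HFD may thus be too many.

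Leaving out 1 library moved the count of called genes to between 236 (without IL4KO_HFD replicate 2) and 2030 (without IL4KO_HFD replicate 3) in diet effect in IL4KO. The range was 185 (IL4KO_HFD replicate 1) and 631 (IL4KO_HFD replicate 2) in IL4KO against WT on HFD and 39 (IL4KO_HFD replicate 2) and 1241 (IL4KO_HFD replicate 3) in dKO against IL4KO on HFD. It was 3 (WT_chow replicate 2) and 8 (WT_chow replicate 1) in diet by genotype IL4KO minus WT and 2130 (dKO_HFD replicate 2) and 4457 (dKO_HFD replicate 4) in diet by genotype dKO minus WT. It was 1293 (IL4KO_HFD replicate 2) and 4190 (dKO_HFD replicate 4) in diet by genotype dKO minus IL4KO. In the other comparisons the ranges were 1751 to 2443 in diet effect in WT, 3942 to 5962 in diet effect in dKO, and 828 to 1139 in IL4KO against WT on chow. They were 5196 to 5660 in dKO against WT on chow, 2403 to 3003 in dKO against WT on HFD and 5071 to 5445 in dKO against IL4KO on chow. The correlation of diet effects in WT and IL4KO ran from 0.41 (without IL4KO_HFD replicate 2) to 0.645 (IL4KO_HFD replicate 3), that in WT and dKO from 0.0489 (WT_chow replicate 1) to 0.184 (WT_chow replicate 3), and that in IL4KO and dKO from -0.0657 (IL4KO_HFD replicate 3) to 0.265 (IL4KO_HFD replicate 2); the cause was not tested. The adjusted p of the list monocyte-derived and lipid-associated macrophage markers in dKO against IL4KO on HFD ran from 2.91e-05 (without dKO_HFD replicate 4) to 0.231 (dKO_HFD replicate 2). That of the list extracellular matrix and stellate cell activation in dKO against IL4KO on HFD ran from 2.53e-12 (without IL4KO_HFD replicate 3) to 0.765 (IL4KO_HFD replicate 2). Both directions reversed without IL4KO_HFD replicate 2 (0.039 and 0.765), and the cause was not tested. The window test of Il10 in dKO against WT on HFD had an odds ratio of 1.74 at 10 Mb and 1.64 at 5 Mb, where the call was lost, and in dKO against IL4KO on chow 1.62 at 10 Mb, 1.58 at 5 Mb and 1.48 at 20 Mb, where it was lost at both. A window of 5 Mb tests fewer genes, and the cause at 20 Mb was not tested.

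Of 178 list calls, fry kept 139 and the estimated correlation 4. Thinning kept 173 of 176, leaving out that pair of libraries kept 166. Leaving out each library in turn kept 1703 of 1783, lost 78 and reversed 2. With the estimated correlation the lists called went from 14 to 0 in diet effect in WT, 8 to 0 in diet effect in IL4KO, 22 to 0 in diet effect in dKO and 4 to 0 in IL4KO against WT on chow. They went from 6 to 0 in IL4KO against WT on HFD, 22 to 0 in dKO against WT on chow, 11 to 1 in dKO against WT on HFD and 23 to 0 in dKO against IL4KO on chow. They went from 16 to 0 in dKO against IL4KO on HFD, 7 to 3 in diet by genotype IL4KO minus WT, 25 to 0 in diet by genotype dKO minus WT and 20 to 0 in diet by genotype dKO minus IL4KO. By list, the comparisons called went from 8 to 2 for de novo lipogenesis, 6 to 1 for circadian clock and 2 to 1 for adipocyte markers. They went to 0 from 10 for type I interferon response, and from 9 for interferon gamma response and antigen presentation. They went to 0 from 8 for fatty acid oxidation and PPARA targets, male-biased liver genes, monocyte-derived and lipid-associated macrophage markers, extracellular matrix and stellate cell activation, cell cycle and oxidative phosphorylation. They went to 0 from 7 for lipid droplets and PPARG targets, cholesterol synthesis, xenobiotic metabolism and cholangiocyte markers, and from 6 for T and NK cell markers, neutrophil markers, hepatocyte markers and NRF2 targets. They fell to 0 from 5 for gluconeogenesis and insulin signalling, bile acid synthesis and transport, acute phase response, inflammatory cytokines and chemokines, type 2 response and alternative macrophage activation, Kupffer cell markers and unfolded protein and integrated stress response. They fell to 0 from 4 for female-biased liver genes, and from 2 for B and plasma cell markers and endothelial cell markers. The null of camera widens where the correlation estimated for a list exceeds the preset 0.01. How far this accounts for the lost calls was not tested. With fry, another test, the lists called went to 5 in diet effect in IL4KO, 1 in IL4KO against WT on HFD, 5 in dKO against IL4KO on HFD and 3 in diet by genotype IL4KO minus WT. The comparisons called went to 2 for cholesterol synthesis, 4 for interferon gamma response and antigen presentation, 6 for type I interferon response, and 5 for monocyte-derived and lipid-associated macrophage markers. They went to 3 for T and NK cell markers, 5 for B and plasma cell markers, 1 for endothelial cell markers, 2 for unfolded protein and integrated stress response and 5 for adipocyte markers, and the cause was not tested. Without that pair of libraries the lists called went to 13 in diet effect in IL4KO, 11 in IL4KO against WT on HFD and 11 in diet by genotype IL4KO minus WT, and inflammatory cytokines and chemokines from 5 to 9 comparisons. After thinning, B and plasma cell markers went from 2 to 0, and the cause was not tested. Leaving out 1 library moved the lists called to between 5 (without WT_chow replicate 1) and 8 (WT_chow replicate 3) in IL4KO against WT on chow, 5 (IL4KO_HFD replicate 1) and 13 (IL4KO_HFD replicate 2) in IL4KO against WT on HFD, and 6 (WT_chow replicate 3) and 11 (IL4KO_HFD replicate 3) in diet by genotype IL4KO minus WT. By list the comparisons called ran from 2 (without dKO_HFD replicate 4) to 7 (dKO_HFD replicate 3) for female-biased liver genes, 3 (dKO_chow replicate 3) to 5 for type 2 response and alternative macrophage activation. They ran from 1 (WT_HFD replicate 2) to 3 (IL4KO_chow replicate 4) for B and plasma cell markers, 1 (IL4KO_HFD replicate 1) to 3 (IL4KO_HFD replicate 3) for endothelial cell markers. They ran from 3 (WT_chow replicate 4) to 6 (WT_HFD replicate 1) for unfolded protein and integrated stress response, 1 (IL4KO_HFD replicate 2) to 2 for adipocyte markers and 0 to 1 (IL4KO_HFD replicate 1) for erythroid markers.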
